A study of Rattus norvegicus with 4 samples.

How the data were processed

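Single-cell RNA sequencing of CD45+ leukocytes from rat kidneys (Rattus norvegicus) was taken as deposited. Per the labels, kidneys were perfused, the 3 kidneys of a group were pooled and digested with collagenase, and CD45+ cells were sorted with DAPI as a second stain. Libraries were made with 10x Chromium 3' chemistry, whose version the labels leave open between v2 and v3. The untransplanted library is given as NC at day 0 with no strain, and the allograft libraries carry a treatment label, K3, which the labels do not explain and which was not used. The deposited values are counts: UMI counts per gene and cell barcode in whole numbers, without normalisation, made by the authors with Cell Ranger 7.1.0. The authors also name Seurat 5.0.3, whose role is not stated. Whether reads in introns were counted is not stated. The deposited barcode and gene tables hold other entries, names and no measurements.

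The gene tables were identical in the 4 libraries and held 32883 features with 28937 symbols. The 267 symbols found on several features were summed. Of the symbols, 6890 are clone names beginning with AABR07, which belong to the assembly before the mRatBN7.2 that the labels name, so no genome positions are given. Fixed symbols absent from the tables were not analysed here, among them Ccr2, Ccl8, Nos2, Itgam, Cd36, Cd79a, Klrb1a, Stat4 and Trac. Of the 595 entries in 28 gene lists 24 had no symbol in the tables, and of the 206 markers of 16 cell classes 11 had none.

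Cells with under 300 genes (339, 289, 257 and 181 barcodes at days 0, 1, 3 and 7) or over 15% mitochondrial UMIs (401, 1172, 1135 and 788) were left out. Doublets were scored per library with Scrublet in scanpy 1.11.5 (30 components), and as many of the highest scores as a rate of 0.8% per 1000 barcodes gives were removed (451, 507, 854 and 936, at rates of 6.14%, 6.49%, 8.37% and 8.72%). The threshold that Scrublet sets itself would have removed 212, 1, 127 and 242. Kept cells held 48891061, 32450855, 64183717 and 71039911 UMIs, with medians of 2199, 1597, 1988 and 1764 genes per cell.

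Kept cells of the 4 libraries were clustered together without batch correction. Counts were scaled to 10000 per cell, logged, and reduced to 2000 variable genes (genes in at least 10 cells, scaled values of at most 10), 30 principal components and 15 neighbours, then clustered with Leiden at resolution 1 and 10 iterations (igraph 0.11.9, scikit-learn 1.9.0, anndata 0.12.19, seed 1). A marker counted as present in a cluster at 1 or more on the log2 scale above the 25th percentile of clusters and in 10% or more of its cells. A cluster took the class with the highest mean marker level, each marker scaled between its lowest and highest cluster. It was left unnamed with fewer than 3 markers of that class present, with as large a share of the markers of the next class, with more markers of another class among its 10 leading genes, or with UMI counts under 1/3 of the library medians and no marker among those 10. Of 27 clusters, 24 were named, in 9 classes, and 3 were left unnamed. Classes are written "-like" since they rest on RNA alone.

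Leading genes of the monocyte/macrophage-like clusters were Hes1 and Adgre4 (cluster 0), Kitlg and Filip1 (1), Fcnb and Vcan (2), Acod1 and Gbp5 (4), Cxcl13 and Mmp12 (6), Ubd and Ass1 (8), Apoe and Spp1 (9), Spc24 and Top2a (19), and Arg1 and Pdpn (22). Those of the T-like clusters were Ccl5 and Gzmm (5), Il17a and Cd40lg (7), Lef1 and Ikzf2 (10), Lag3 and Tnfrsf9 (13), and Ube2c and Mki67 (18). Neutrophil-like clusters were led by Car4 and Lcn2 (3) and Camp and S100a8 (16). Dendritic cell-like clusters were led by Ccl17 and Rab30 (12), Xcr1 and Clec9a (20), and Cacnb3 and Fscn1 (21). The B-like cluster was led by Ebf1 and Cd79b (11), the plasmacytoid one by Siglech and Bcl11a (14), the NK-like one by Klri1 and Clnk (17), the innate lymphoid one by Il1rl1 and Gata3 (24) and the tubular one by Epcam and Slc12a1 (25). Unnamed were cluster 15 (low UMI counts), cluster 23 (Col1a1 and Emcn, with mesenchymal and endothelial markers alike) and cluster 26 (Ccr6 and Il23r). Many genes named in library comparisons, such as Vcan, Fn1, Ccl7, Cxcl11, Lef1, Ube2c and Gzmb, also lead clusters the libraries fill unequally.

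UMIs were summed over the cells of a class in a library and given as CPM of that sum. Classes with at least 100 kept cells in both libraries were compared, and ligand or receptor values are given from 20 cells. Log2 ratios of genes ranked by the rule and of list members used a pseudocount of 10 CPM, and folds and their intervals used none. A list member counted as measured at 5 or more UMIs over both libraries and 10 CPM or more in at least 1, and a list needed 3 such members. The haemoglobin RNA and sex-linked lists had fewer and gave no result. The median log2 ratio of a list was set beside 10000 random lists of the same size drawn from windows of 200 genes of like mean CPM. This gave 190 list results, 122 of them in the lowest or highest 2.5% of random lists. Genes are not independent of each other, so these percentiles are a description and not a test. For the share of cells with a UMI of a gene, each cell was thinned to 1300 UMIs, and 1874 cells with fewer (133, 561, 750 and 430) were left out. Intervals within clusters used 200 Poisson redraws for list medians.

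Gene names in the text follow a rule. Among genes with 100 CPM or more in either library, the 5 furthest up and the 5 furthest down were named in T-like, NK-like and monocyte/macrophage-like cells, and 3 and 3 in other classes. Left out were mitochondrial genes, ribosomal protein genes (Rps, Rpl, Mrps, Mrpl), immunoglobulin and T cell receptor segments, haemoglobins, genes without a symbol (ENSRNOG, LOC, RGD, AABR, AC and NEWGENE names) and markers of another class. Genes whose CPM in the class, in the library where it is higher, lay under 20% of their highest CPM in another named class of that library were left out too, since free RNA can give that. Also named were up to 4 members per list and comparison (2 per direction, or 4 in the direction of the median), and always Ccl3, Ccl4, Ccl5, Ccr5 and Ccr1. The grouping, filters, markers, gene lists, naming rule and most alternatives were chosen before the data were examined.

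The calculation of intervals and list percentiles was checked on Poisson counts simulated from the joint day 0 and day 7 profile at both depths. There, 200 genes were changed 2-fold or 4-fold. The 95% intervals covered the true ratio for 95.65% of 7495 genes in T-like and 95.18% of 7057 genes in monocyte/macrophage-like cells, and 4.5% and 4.0% of 200 unchanged lists lay outside the percentiles. Alternatives were a mitochondrial limit of 10% or 25%, at least 500 genes per cell, doublets kept, Leiden resolution 0.5 or 2, 50 components, classes given cell by cell from markers, median-of-ratios scaling, a mean of single cells, a total without the 10 genes with the most UMIs, pseudocounts of 1 and 50 CPM, no CPM minimum, shares without thinning and shares of named cells only. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.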

Results

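Single-cell RNA sequencing was done on CD45+ leukocytes sorted from rat kidneys. CD45 is the surface protein carried by nearly all leukocytes. The 4 libraries fell into 4 groups of 1 library each: untransplanted kidneys (day 0) and kidney allografts taken 1, 3 and 7 days after transplantation from Wistar donors into SD recipients. Each library was made from 3 kidneys pooled before sorting. The series gives a sample size of 3 per group, but with pooled kidneys no value per animal exists. The strain of the untransplanted rats is not stated. The series states that no drug was given to the allograft groups. The series title names the ligand Ccl3 and its receptor Ccr5, so both were followed by cell class and day.

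The deposited tables held 7681, 8110, 10463 and 10905 cell barcodes for the untransplanted, day 1, day 3 and day 7 libraries, with 57176130, 38156694, 77543831 and 86368885 UMIs (unique molecular identifiers, each a counted transcript). After the filters 6505, 6200, 8273 and 9028 cells remained (84.7%, 76.4%, 79.1% and 82.8% of the barcodes), with medians of 6718, 3866.5, 5508 and 5263 UMIs per cell. With 1 library per group, no test between groups exists, and no p-value or standard error is given. Brackets hold 95% intervals, exact Clopper-Pearson for shares, exact Poisson for CPM, and conditional exact for folds. They cover counting error only, not differences among cells, animals, digestions or sorts. CPM is the UMI count of a gene in a class of a library, scaled by the total UMIs of that class to the usual fixed sum. A fold is the CPM of a class in an allograft library over its CPM in the same class of the untransplanted library.

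Monocyte/macrophage-like cells made up most of the sorted cells in the untransplanted, day 1 and day 3 libraries, and the share of neutrophil-like cells was higher in each allograft library than in the untransplanted one. Monocyte/macrophage-like cells were 62.4% [61.3 to 63.6] of kept cells in the untransplanted library and 67.5% [66.3 to 68.6], 54.7% [53.6 to 55.7] and 48.0% [46.9 to 49.0] at days 1, 3 and 7, with log2 ratios of 0.11, -0.19 and -0.38. Neutrophil-like cells went from 1.14% [0.894 to 1.43] to 5.53% [4.98 to 6.13], 3.63% [3.23 to 4.05] and 21.1% [20.3 to 21.9], which are 4.86-, 3.19- and 18.5-fold of the untransplanted share. T-like cells were 18.2% [17.3 to 19.2], 9.39% [8.67 to 10.1], 20.2% [19.3 to 21.1] and 21.1% [20.3 to 22.0], with log2 ratios of -0.96, 0.15 and 0.22. Plasmacytoid dendritic cell-like cells, the class known for making type I interferon, were 0.384% [0.249 to 0.567], 3% [2.59 to 3.46], 7.18% [6.63 to 7.76] and 0.487% [0.354 to 0.654], so that day 3 stood at 18.7-fold. Other dendritic cell-like cells were 5.24% [4.71 to 5.81], 6.44% [5.84 to 7.08], 6.24% [5.73 to 6.78] and 0.144% [0.0767 to 0.246]. B-like cells were 2.26% [1.91 to 2.65], 2% [1.67 to 2.38], 3.42% [3.04 to 3.84] and 4.21% [3.804 to 4.64], and NK-like cells 5.75% [5.20 to 6.34], 0.581% [0.407 to 0.803], 1.33% [1.09 to 1.60] and 2.02% [1.74 to 2.33].

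Innate lymphoid cell-like cells were 1.21%, 0.5%, 0.133% and 0.0111% of kept cells, tubular epithelial cell-like cells 0.615%, 0.0968%, 0.532% and 0.188%, and cells in 3 unnamed clusters 2.75%, 4.98%, 2.68% and 2.77%. The CD45 sort sets which cells enter these shares, and the kept classes differed in depth: neutrophil-like cells had medians of 1695, 1565, 1029.5 and 3007 UMIs against 7099, 3985.5, 4986.5 and 8480 in monocyte/macrophage-like cells, so the minimum of 300 genes did not act on both classes alike. Naming each cell by its own markers, without clusters, turned the monocyte/macrophage-like log2 ratio at day 1 from 0.11 to -0.09 and moved the neutrophil-like one at day 1 from 2.28 to 3.39.

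The clusters behind a class differed between libraries, and a cluster made mostly of 1 library is not told apart from that library. Of the monocyte/macrophage-like cells, cluster 1 held 92.2%, 0.0239%, 0.0885% and 0.0462% in the untransplanted, day 1, day 3 and day 7 libraries. Cluster 0 held 6.60%, 58.2%, 30.1% and 1.36%, cluster 2 0.542%, 13.05%, 55.9% and 4.53%, and cluster 6 0.123%, 27.8%, 4.73% and 0.0924%. At day 7 clusters 4, 8, 9 and 22 held 35.4%, 27.9%, 26.8% and 3.83%, and at day 3 cluster 19, led by proliferation genes, held 8.14%. Of the T-like cells, cluster 5, led by cytotoxic and Cd8 genes, held 58.9%, 36.1%, 7.002% and 28.1%, cluster 7 14.02%, 30.6%, 42.2% and 11.1% and cluster 10 21.7%, 30.8%, 34.4% and 7.60%. Cluster 13 held 1.52%, 0.344%, 0.419% and 44.2% and the proliferating cluster 18 3.89%, 2.23%, 16.04% and 8.91%. Of the dendritic cell-like cells, cluster 12 held 43.7%, 55.4%, 99.0% and 92.3%, cluster 20 56.0%, 0%, 0.388% and 0% and cluster 21 0.293%, 44.6%, 0.581% and 7.69%. Neutrophil-like cells were in cluster 16 for 95.9%, 81.3%, 99.3% and 2.89% and in cluster 3 for 4.05%, 18.7%, 0.667% and 97.1%. Comparisons within these classes are therefore between libraries that different clusters fill.

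Ccl3 (MIP-1 alpha), a chemokine that binds Ccr5 and Ccr1, was most abundant per UMI in the untransplanted and day 7 libraries. In monocyte/macrophage-like cells its level was 4669 [4645 to 4694], 1962 [1943 to 1980.5], 821 [812 to 830.4] and 3353 [3336 to 3369] CPM at days 0, 1, 3 and 7, and this class carried 74.8%, 92.3%, 77.7% and 56.7% of the Ccl3 UMIs of each library. In T-like cells it was 4539 [4492 to 4585], 426 [405 to 448], 344 [334 to 354] and 3739 [3707 to 3771] CPM. In NK-like cells it was 3038 [2962 to 3116], 1421 [1261 to 1596], 2373 [2255 to 2495] and 3989 [3856 to 4126] CPM (36 cells at day 1). In neutrophil-like cells it was 3839 [3513 to 4188], 616 [559 to 677], 334 [279.7 to 396] and 9708 [9631 to 9785] CPM (74 cells at day 0), so that neutrophil-like cells held 21.9% of the day 7 Ccl3 UMIs. B-like cells had 1994 [1890.4 to 2101], 213 [170.0 to 265], 161 [145 to 179] and 1877 [1804 to 1952] CPM. Dendritic cell-like cells had 304 [289.9 to 319.6], 175 [163 to 187] and 186 [176 to 196] CPM at days 0, 1 and 3.

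Thinned to 1300 UMIs each, 78.1%, 53.4%, 37.1% and 75.4% of monocyte/macrophage-like cells and 62.0%, 22.6%, 10.1% and 69.9% of T-like cells had a Ccl3 UMI at days 0, 1, 3 and 7. The shares without thinning were 90.2%, 73.8%, 54.5% and 93.4% and 80.2%, 54.1%, 21.5% and 87.2%, at median depths of 7099, 3985.5, 4986.5 and 8480 and 5821, 4923, 6871 and 5524.5 UMIs. As a background for Ccl3, thinned tubular epithelial cell-like cells, which should lack it, had shares of 21.2% at day 0 and 2.70% at day 3 (median depths 7865.5 and 9716.5 UMIs). Dendritic cell-like and plasmacytoid dendritic cell-like cells were not shown to lack Ccl3, so their shares are a comparison and do not measure free RNA. Dendritic cell-like cells had 19.7%, 12.5% and 8.71% at days 0, 1 and 3 (median depths 16185, 10444 and 14812.5 UMIs). Plasmacytoid dendritic cell-like cells had 23.7% at day 1 and 5.09% at day 3 (median depths 2650 and 3311 UMIs). At day 7 this class was the only comparison (40 of 44 cells thinned), at 17.5% [7.34 to 32.8] (median depth 10056.5 UMIs). These shares do not decide how much of the Ccl3 of T-like cells was free RNA. The Ccl3 share of T-like cells at day 1 (22.6% [19.3 to 26.3]) lay at the plasmacytoid level and above the dendritic one. At day 3 (10.1% [8.68 to 11.6]) it lay above the plasmacytoid level (5.09% [3.35 to 7.37]), and its interval overlapped the dendritic one (8.71% [6.40 to 11.5]). T-like cells of cluster 5 had 7672 CPM of Ccl3 untransplanted, 1009 at day 1 and 2583 at day 3. The shares of monocyte/macrophage-like cells lay above all of these classes at days 0, 1 and 3.

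Ccl4 and Ccl5, the other main ligands of Ccr5, were highest in lymphocytes. Ccl4 stood at 9854 [9785 to 9923], 733 [705 to 762], 813 [798 to 829] and 9424 [9373 to 9475] CPM in T-like cells at days 0, 1, 3 and 7. In monocyte/macrophage-like cells Ccl4 was 7911 [7879 to 7942], 776 [764 to 788], 311 [305 to 317] and 1359 [1348 to 1369.5] CPM and in NK-like cells 9251 [9117 to 9385], 1824 [1642 to 2021], 5789 [5605 to 5978] and 9033 [8832 to 9238] CPM. Ccl5 stood at 10278 [10137 to 10419.7], 4498 [4209.6 to 4801], 13591 [13307 to 13879] and 16214 [15943 to 16488] CPM in NK-like cells. In T-like cells Ccl5 was 4156 [4112 to 4201], 295 [277 to 313], 948 [932 to 965] and 5011 [4974 to 5048] CPM. Monocyte/macrophage-like cells had 28.4, 9.36, 7.81 and 30.0 CPM, so free RNA is not excluded for their Ccl5 folds. Ccr5 was spread over several classes, and in T-like, NK-like and monocyte/macrophage-like cells it differed less between libraries than Ccl3 did in T-like and monocyte/macrophage-like cells. It stood at 216 [206 to 226], 105 [94.5 to 116], 133 [126 to 139] and 206 [199 to 214] CPM in T-like cells, 133 [129 to 137], 109 [105 to 113], 175 [170.3 to 179] and 135 [132 to 138] CPM in monocyte/macrophage-like cells and 263, 253, 196 and 181 CPM in NK-like cells. Ccr5 was at 43.0 [37.6 to 48.9], 99.9 [91.0 to 109] and 179.7 [170.2 to 189.5] CPM in dendritic cell-like cells at days 0, 1 and 3. Neutrophil-like cells had 11.5, 12.6 and 4.46 CPM of Ccr5 at days 1, 3 and 7. After thinning, 21.8%, 12.9%, 14.2% and 23.2% of T-like and 13.4%, 8.99%, 17.6% and 13.4% of monocyte/macrophage-like cells had a Ccr5 UMI. Of 205, 95 and 1829 neutrophil-like cells, 0.488%, 1.05% and 0.765% had one at days 1, 3 and 7. Without thinning the shares were 49.6%, 30.6%, 40.0% and 53.5% of T-like and 37.1%, 24.1%, 46.5% and 48.7% of monocyte/macrophage-like cells. Ccr1, which also binds Ccl3 and Ccl5, was at 565, 605, 545 and 504 CPM in neutrophil-like cells and 2.67 [2.12 to 3.32], 143 [138 to 148], 119 [115 to 122] and 36.9 [35.2 to 38.7] CPM in monocyte/macrophage-like cells. T-like cells had 0.2498, 7.03, 2.86 and 4.90 CPM of Ccr1. In NK-like cells Ccr1 was at 0 [0 to 1.85], 0 [0 to 5.75] and 0 [0 to 4.37] CPM at days 0, 3 and 7, and at 9.94 [1.20 to 35.9] CPM (2 UMIs) in the 36 cells of day 1. The gene identifiers were ENSRNOG00000011205 (Ccl3), ENSRNOG00000011406 (Ccl4), ENSRNOG00000010906 (Ccl5), ENSRNOG00000049115 (Ccr5) and ENSRNOG00000006715 (Ccr1). Positions are not given, since labels and gene names differ in assembly.

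**Figure D1:**
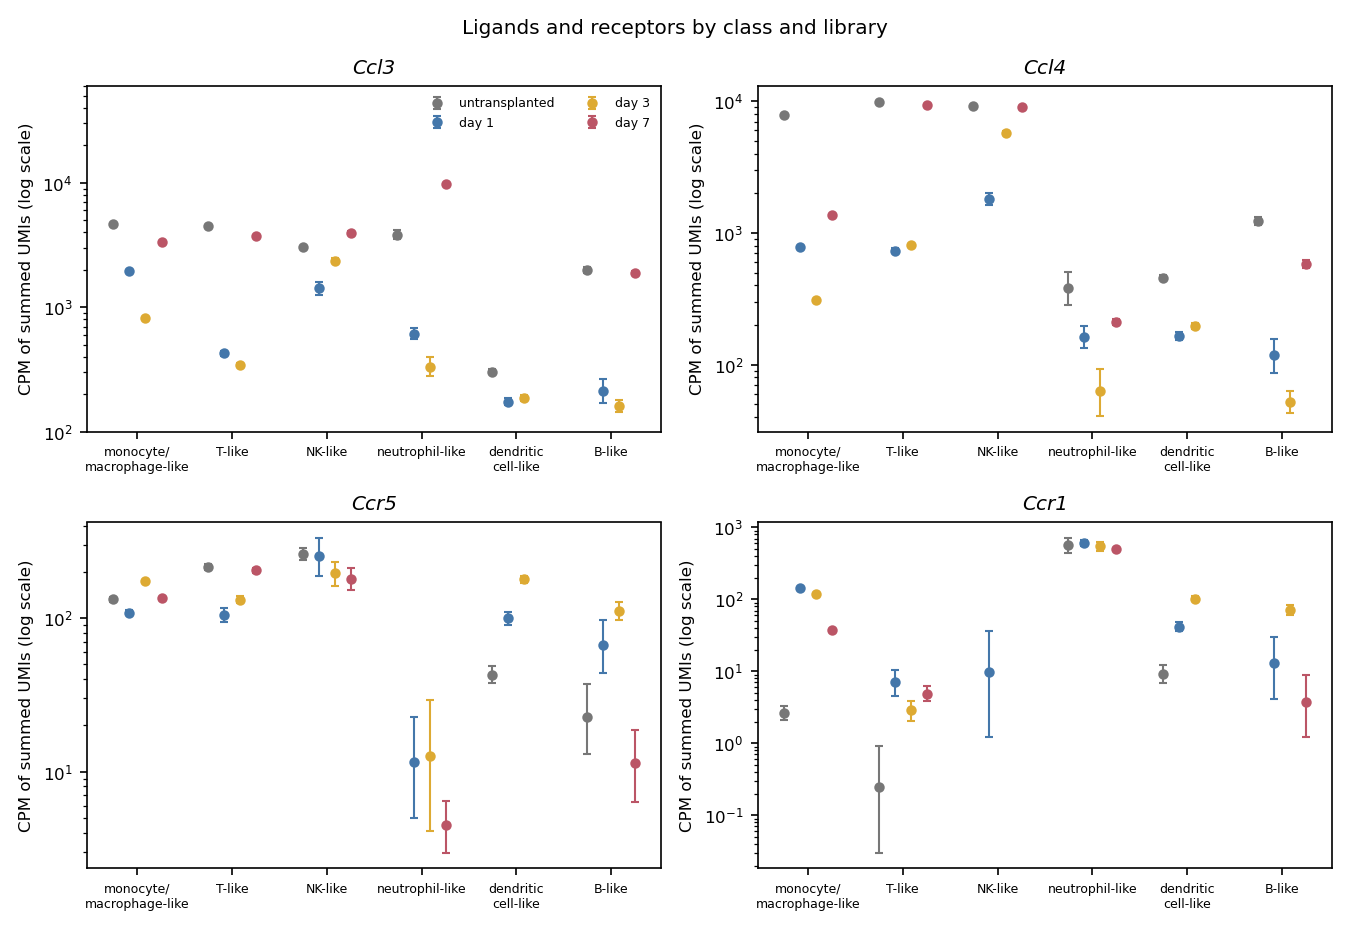
CPM of Ccl3, Ccl4, Ccr5 and Ccr1 (log axis) in 6 cell classes at days 0, 1, 3 and 7, with exact 95% Poisson intervals, 1 library per day. Values of 0 and classes with under 20 cells are not drawn. Ccl3 in T-like cells was 4539 CPM at day 0, 426 at day 1, 344 at day 3 and 3739 at day 7.

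Monocyte/macrophage-like cells of the allografts had higher Ccl7, Slpi and Ccr1 RNA at day 1, and lower Ccl4 and Ccl3 RNA. In this class at day 1 (4184 cells against 4062 untransplanted), the genes furthest above the untransplanted library, ranked by log2 ratio with a pseudocount of 10 CPM, were Slfn4 37.4-fold [36.2 to 38.5], Slpi 40.2-fold [37.6 to 43.0], Ccl7 58.4-fold [51.6 to 66.3], Vcan 59.1-fold [52.0 to 67.5] and Prdx5 24.6-fold [23.6 to 25.6]. Slpi is a secreted inhibitor of leukocyte proteases, Ccl7 a chemokine that attracts monocytes, Vcan a proteoglycan typical of monocytes and Prdx5 a peroxidase. Furthest below were Rasd1 0.0128-fold [0.0109 to 0.0150], Rgs1 0.0285-fold [0.0276 to 0.0294], Cxcl1 0.0280-fold [0.0264 to 0.0296], Kitlg 0.0282-fold [0.0262 to 0.0304] and Cdc14a 0.0294-fold [0.0266 to 0.0323]. Rgs1 dampens G protein signalling, Cxcl1 attracts neutrophils and Kitlg is the ligand of the receptor Kit. Ccl3 stood at 0.420-fold [0.416 to 0.425], Ccl4 at 0.0981-fold [0.0966 to 0.0997]. Ccl5 stood at 0.329-fold [0.281 to 0.384], Ccr5 at 0.821-fold [0.780 to 0.864] and Ccr1 at 53.6-fold [43.0 to 67.7]. The Ccl3 level depended on the cluster: at day 1 it was 3472 CPM in cluster 0, 919 in cluster 2 and 869 in cluster 6, against 3740 in cluster 0 and 4759 in cluster 1 of the untransplanted library.

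At day 3 (4522 cells) the genes furthest above were Slpi 39.9-fold [37.3 to 42.6], Vcan 60.1-fold [52.9 to 68.6], Cxcl11 142-fold [112 to 183], Upp1 55.6-fold [48.4 to 64.3] and Prdx5 25.2-fold [24.2 to 26.2]. Cxcl11 is an interferon-induced ligand of Cxcr3, and Upp1 is uridine phosphorylase. Furthest below were Kitlg 0.00719-fold [0.00640 to 0.00805], Rasd1 0.0126-fold [0.0111 to 0.0142], Ccl4 0.0393-fold [0.0386 to 0.0401], Rgs1 0.0433-fold [0.0424 to 0.0442] and Filip1 0.0207-fold [0.0180 to 0.0237]. Ccl3 stood at 0.176-fold [0.174 to 0.178] and Ccl5 at 0.275-fold [0.239 to 0.315], Ccr5 at 1.31-fold [1.26 to 1.37] and Ccr1 at 44.5-fold [35.8 to 56.2]. Ccl3 was 3018 CPM in cluster 0, 713 in cluster 2, 262 in cluster 6 and 170 in the proliferating cluster 19. As a mean of single cells in place of a sum, the Ccl3 log2 ratio at day 3 was -1.55, against -2.51 from the sums.

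At day 7 (4329 cells) the genes furthest above were Acod1 6566-fold [3017 to 17893], Ubd 1081-fold [752 to 1614], Apoe 66.1-fold [64.7 to 67.6], Spp1 63.3-fold [58.3 to 68.8] and Ass1 73.5-fold [65.5 to 82.8]. Acod1 makes itaconate, Ubd is an interferon-induced ubiquitin-like protein, Apoe carries lipids, Spp1 is osteopontin and Ass1 makes argininosuccinate for arginine synthesis. Apoe reached 17466 CPM from 264. Furthest below were Kitlg 0.00396-fold [0.00346 to 0.00453], Rasd1 0.00700-fold [0.00604 to 0.00807], Zbtb16 0.00507-fold [0.00411 to 0.00619], Basp1 0.0267-fold [0.0253 to 0.0280] and Filip1 0.00647-fold [0.00520 to 0.00797]. Ccl3 stood at 0.718-fold [0.713 to 0.723], Ccl4 at 0.172-fold [0.170 to 0.173]. Ccl5 stood at 1.06-fold [0.969 to 1.15], Ccr5 at 1.02-fold [0.976 to 1.06] and Ccr1 at 13.8-fold [11.1 to 17.5]. Ccl3 was 8249 CPM in cluster 4, 7225 in cluster 22, 3483 in cluster 2, 2096 in cluster 8 and 1965 in cluster 9. Its direction against the untransplanted library was not settled: the log2 ratio was -0.48 by CPM, 0.0038 with median-of-ratios scaling and 0.014 as a mean of single cells. Kitlg, Filip1, Rasd1 and Zbtb16 are among the 10 leading genes of cluster 1, and Acod1, Ubd, Apoe, Spp1 and Ass1 lead clusters that day 7 cells fill, so for them the libraries and the clusters give the same comparison.

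Fixed gene lists were compared by the median log2 ratio of their measured members, with its percentile among 10000 random lists of like level. A median in the lowest or highest 2.5% of random lists is taken as outside what they gave. Medians below are at days 1, 3 and 7 unless days are named, and "members" are those measured. The median log2 ratio of all genes, which scaling by the total leaves in, was 0.15, 0.14 and -0.48 in monocyte/macrophage-like cells, 0.13, 0.10 and -0.04 in T-like cells, 0.17, -0.10 and -0.08 in B-like cells, 0.23 and 0.30 in dendritic cell-like cells (days 1 and 3), and 0.10 and -0.02 in NK-like cells (days 3 and 7). The percentiles are relative to genes of like level and so largely free of that shift.

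In monocyte/macrophage-like cells, monocyte genes were higher in all 3 allograft libraries. The monocyte list had median log2 ratios of 2.27, 1.75 and 2.15 (percentiles 100, 100 and 100). 14 of 19, 15 of 19 and 14 of 18 members were at least 2-fold higher and 0, 0 and 0 lower. Members included S100a8 209.7-fold [177 to 250.5] and S100a9 78.7-fold [71.4 to 87.0] at day 1, Fn1 24.8-fold [23.3 to 26.3] at day 3 and Plac8 14.2-fold [13.8 to 14.5] at day 7. S100a8 and S100a9 were at 926 and 1065 CPM at day 1, against 80613 and 127908 CPM in neutrophil-like cells of that library, so free RNA of neutrophils is not excluded for these 2 members. Genes of resident macrophages had median log2 ratios of -0.71, -1.26 and -0.35 (percentiles 0.01, 0 and 30.7). 0 of 17, 0 of 17 and 2 of 18 members were at least 2-fold higher and 7, 10 and 6 lower. Members included C1qc at 0.134-fold [0.131 to 0.136] and C1qb at 0.162-fold [0.159 to 0.165] at day 3. Lyve1 stood at 1.73-fold [1.62 to 1.85] at day 3 and 0.0319-fold [0.0244 to 0.0411] at day 7, and Apoe at 0.0326-fold [0.0281 to 0.0377] at day 1 before its high level at day 7. The lipid-associated and repair macrophage list had median log2 ratios of 1.53, 1.55 and 2.00 (percentiles 100, 100 and 100). 17 of 25, 17 of 25 and 20 of 26 members were at least 2-fold higher and 1, 2 and 1 lower. Members included Spp1 at 15.7-fold [14.4 to 17.1] at day 3 and Gpnmb at 12.96-fold [12.4 to 13.5] and Ctsd at 12.6-fold [12.04 to 13.3] at day 7. Arg1, which breaks down arginine, went from 0.527 to 55.6 CPM at day 1 and 286 CPM at day 7. The interferon-stimulated list had median log2 ratios of 1.12, 0.49 and 1.28 (percentiles 100, 99.2 and 100). 22 of 38, 10 of 31 and 18 of 31 members were at least 2-fold higher and 0, 0 and 0 lower. Its leading members were Isg15 29.7-fold [26.9 to 32.9] and Irf7 16.1-fold [14.7 to 17.6] at day 1, Cxcl9 50.02-fold [40.1 to 63.2] and Gbp2 7.57-fold [7.01 to 8.18] at day 3 and Gbp2 25.1-fold [23.3 to 27.0] and Gbp5 31.5-fold [28.4 to 35.0] at day 7.

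Energy genes of this class were also higher than at day 0. The glycolysis and hypoxia list had median log2 ratios of 1.11, 1.29 and 1.96 (percentiles 100, 100 and 100). 13 of 23, 13 of 23 and 17 of 24 members were at least 2-fold higher and 2, 1 and 0 lower. Members included Ldha 5.96-fold [5.78 to 6.16] at day 1 and Pgk1 15.4-fold [14.7 to 16.1] and Vegfa 13.4-fold [12.1 to 14.7] at day 7, while Ndrg1 was 0.215-fold [0.203 to 0.227] at day 1. The oxidative phosphorylation list had median log2 ratios of 0.85, 1.03 and 0.82 (percentiles 99.8, 100 and 99.9). 9 of 24, 13 of 24 and 11 of 24 members were at least 2-fold higher and 0, 0 and 0 lower. Members included Cox5a 4.37-fold [4.24 to 4.51] and Atp5mc1 3.09-fold [2.99 to 3.19] at day 3. The proliferation list had median log2 ratios of 0.25, 1.49 and 0.29 (percentiles 81.4, 100 and 100). 0 of 19, 34 of 39 and 2 of 23 members were at least 2-fold higher and 0, 0 and 0 lower. Members included Ube2c 17.2-fold [15.04 to 19.7], Top2a 11.7-fold [10.2 to 13.4] and Mki67 9.17-fold [8.25 to 10.2] at day 3. The proinflammatory cytokine list had median log2 ratios of -0.79, 0.38 and 1.38 (percentiles 0.27, 81.8 and 100). 0 of 9, 1 of 10 and 6 of 11 members were at least 2-fold higher and 3, 1 and 1 lower. Il1b stood at 0.282-fold [0.276 to 0.287] at day 1, and at day 7 Il1a stood at 29.4-fold [24.1 to 36.3], Il6 at 23.6-fold [18.3 to 31.1] and Ptgs2, the inducible cyclooxygenase, at 8.83-fold [8.38 to 9.30]. The chemokine ligand list had median log2 ratios of 1.82, -0.06 and 0.47 (percentiles 100, 18.8 and 98.5). 11 of 19, 8 of 18 and 6 of 16 members were at least 2-fold higher and 5, 8 and 2 lower. Members included Ccl2 14.1-fold [13.6 to 14.7] and Ccl12 27.3-fold [25.3 to 29.4] but Cxcl2 0.0495-fold [0.0485 to 0.0507] at day 1, and Cxcl10 13.7-fold [12.98 to 14.5] and Cxcl9 41.0-fold [32.8 to 51.7] at day 7. Complement genes had median log2 ratios of 0.27, -0.08 and 1.17 (percentiles 77.8, 19.4 and 100). 3 of 13, 3 of 14 and 9 of 17 members were at least 2-fold higher and 2, 4 and 3 lower. Members included C1r 17.3-fold [14.8 to 20.4], Cfd 13.3-fold [11.7 to 15.2] and Cfh 0.187-fold [0.183 to 0.192] at day 7. Scavenger and phagocytic receptors had median log2 ratios of 0.48, -0.04 and 0.98 (percentiles 91.7, 24.8 and 100). 4 of 13, 5 of 13 and 7 of 15 members were at least 2-fold higher and 4, 3 and 3 lower. Members included Fcgr2b 15.8-fold [14.4 to 17.4] and Mrc1 0.114-fold [0.106 to 0.122] at day 7.

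For co-stimulation and dendritic cell maturation, medians in monocyte/macrophage-like cells were 0.11, -0.33 and 0.40 (percentiles 48.5, 2.66 and 95.2), with Cd86 0.0963-fold [0.0905 to 0.102], Cd83 0.0514-fold [0.0499 to 0.0529] and Cd274 3.87-fold [3.66 to 4.09] at day 1. Those of MHC class I presentation were 0.41, 0.17 and 0.94 (percentiles 89.1, 54.8 and 99.96), with Psmb9 4.10-fold [3.99 to 4.21] and Tap1 3.302-fold [3.15 to 3.46] at day 7. Chemokine receptors gave 0.07, 0.21 and -0.20 (percentiles 47.4, 55.3 and 54.6) and the Ccl3-Ccr5 axis list -0.99, -1.11 and 0.02 (percentiles 1.58, 1.32 and 63.5). Tubular RNA, a sign of RNA from outside the sorted cells, gave -0.30, -0.07 and -0.15 (percentiles 12.7, 26.6 and 65.8). Genes of dissociation and stress had median log2 ratios of -0.73, -0.69 and -0.89 (percentiles 0.16, 0.31 and 0.165). 0 of 21, 0 of 21 and 0 of 21 members were at least 2-fold higher and 9, 6 and 10 lower. Members included Fosb at 0.316-fold [0.312 to 0.320] and Zfp36 at 0.228-fold [0.224 to 0.231] at day 1 and Hspa1b at 0.0782-fold [0.0770 to 0.0795] at day 7, so that the untransplanted library was higher in this list than each allograft library. With no CPM minimum the proinflammatory median at day 1 turned to 0.03, the interferon median at day 3 (0.20) and the chemokine ligand median at day 7 (0.06) came within random lists, as did the Ccl3-Ccr5 axis at day 3 (-0.56). With a pseudocount of 50 CPM the Ccl3-Ccr5 axis at days 1 and 3 (-0.40 and -0.44) and the chemokine ligands at day 7 (0.26) did so too.

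**Figure D2:**
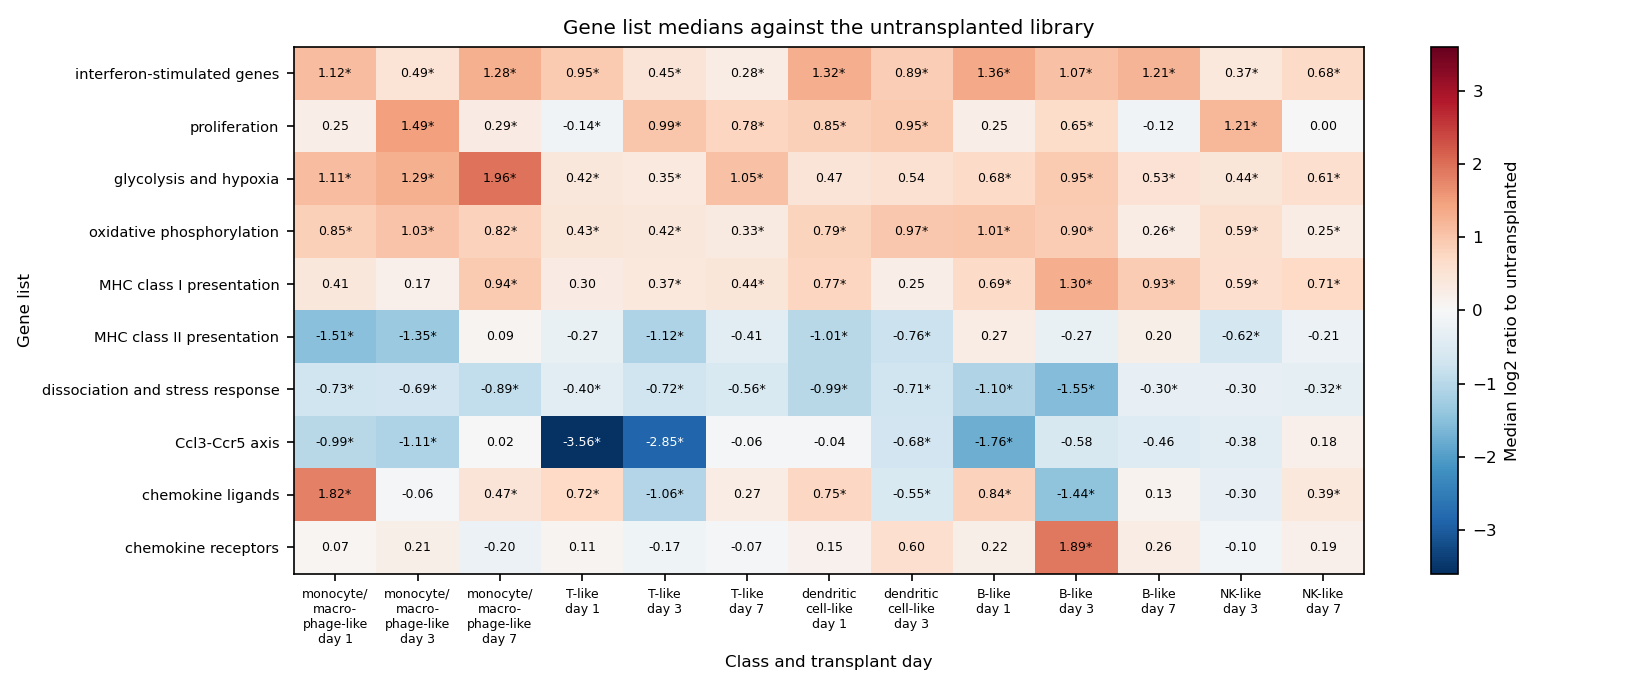
Median log2 ratio to the untransplanted library (colour and number) of 10 gene lists (rows) in 5 cell classes by transplant day (columns), 1 library per day. An asterisk marks a median in the lowest or highest 2.5% of random lists. Interferon-stimulated genes were above 0 and the stress list below 0 in all 13 columns, which share 1 untransplanted library.

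In T-like cells at day 1 (582 cells against 1184), the genes furthest above were Ifi27 6.24-fold [5.74 to 6.79], Irf7 6.58-fold [5.60 to 7.74], Slc1a5 5.19-fold [4.602 to 5.86], RT1-T24-3 5.21-fold [4.40 to 6.17] and Xcl1 4.04-fold [3.87 to 4.23]. Ifi27 and Irf7 are interferon-induced, Slc1a5 carries glutamine and Xcl1 is the ligand of Xcr1 on cross-presenting dendritic cells. Furthest below were Gzmk 0.0524-fold [0.0436 to 0.0624], Ccl5 0.0709-fold [0.0666 to 0.0754], Ccl4 0.0744-fold [0.0715 to 0.0774], Nr4a3 0.0829-fold [0.0756 to 0.0906] and Ccl3 0.0938-fold [0.0891 to 0.0988], where Gzmk is a granzyme and Nr4a3 a transcription factor induced by T cell receptor signals. Ccr5 stood at 0.485-fold [0.433 to 0.543], and Ccr1 at 28.1-fold [7.01 to 245] on 25 and 2 UMIs, for which free RNA is not excluded. Cluster 5, led by Ccl5, Gzmm and Gzmk, was 58.9% of the untransplanted class and 36.1% at day 1.

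At day 3 (1671 cells) the genes furthest above were Ccl1 28.7-fold [21.8 to 38.6], Itgb7 4.24-fold [3.75 to 4.80], Ube2c 4.0001-fold [3.61 to 4.44], Tnfrsf4 4.31-fold [3.77 to 4.96] and RT1-T24-1 3.84-fold [3.49 to 4.25]. Itgb7 is an integrin of gut homing, Ube2c acts in mitosis and Tnfrsf4 is the co-stimulatory receptor OX40. Furthest below were Ccl3 0.0757-fold [0.0734 to 0.0781], Ccl4 0.0825-fold [0.0809 to 0.0842], Gzma 0.0565-fold [0.0485 to 0.0656], Gzmb 0.0704-fold [0.0610 to 0.0810] and Jmy 0.149-fold [0.140 to 0.159]. Ccl5 stood at 0.228-fold [0.224 to 0.233], Ccr5 at 0.614-fold [0.574 to 0.656] and Ccr1 at 11.4-fold [2.96 to 98.0] on 38 and 2 UMIs. Cluster 5 held 7.00% of the class at day 3 and clusters 7 and 10 held 42.2% and 34.4%.

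At day 7 (1908 cells) T-like cells had high levels of inhibitory and cytotoxic genes. Furthest above were Slc27a2 587-fold [269.7 to 1601], Tnfrsf9 33.3-fold [29.4 to 37.9], Clmp 126-fold [76.5 to 226], Lag3 23.3-fold [21.4 to 25.4] and Cck 46.3-fold [31.3 to 71.8]. Tnfrsf9 is the co-stimulatory receptor 4-1BB and Lag3 an inhibitory receptor. Furthest below were Slc9a9 0.153-fold [0.139 to 0.168], Rab3ip 0.115-fold [0.0971 to 0.137], Zbtb20 0.190-fold [0.175 to 0.205], Lef1 0.209-fold [0.194 to 0.224] and Nr4a3 0.243-fold [0.236 to 0.251], where Lef1 is a transcription factor of naive T cells. Ccl3 stood at 0.824-fold [0.813 to 0.835], Ccl4 at 0.956-fold [0.948 to 0.965]. Ccl5 was at 1.21-fold [1.19 to 1.22], Ccr5 at 0.953-fold [0.898 to 1.01] and Ccr1 at 19.6-fold [5.23 to 165] on 69 and 2 UMIs. Slc27a2, Tnfrsf9, Clmp, Lag3, Cck, Gzmb, Prf1 and Ctla4 lead cluster 13 (44.2% of the class at day 7, 1.52% at day 0). RT1 genes, such as the T24 group, differ between rat strains, and that of the untransplanted rats is not stated.

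The cytotoxic list of T-like cells had median log2 ratios of -0.36, -1.27 and 0.64 (percentiles 1.44, 0 and 99.99). 0 of 18, 0 of 18 and 7 of 19 members were at least 2-fold higher and 6, 10 and 1 lower. Gzmb stood at 0.114-fold [0.0916 to 0.140] at day 1 and 0.0704-fold [0.0610 to 0.0810] at day 3 but 6.38-fold [6.09 to 6.69] at day 7, and Prf1 (perforin) at 5.02-fold [4.76 to 5.31] at day 7. Inhibitory receptor and exhaustion genes had median log2 ratios of -0.19, -0.25 and 0.85 (percentiles 5.98, 1.12 and 100). 1 of 16, 0 of 17 and 6 of 16 members were at least 2-fold higher and 6, 4 and 1 lower. Members included Ctla4 4.95-fold [4.59 to 5.33], Havcr2 4.93-fold [4.40 to 5.55] and Pdcd1 4.15-fold [3.63 to 4.75] at day 7. The regulatory T cell list had median log2 ratios of 0.04, 0.13 and 0.85 (percentiles 42, 66.5 and 100). 2 of 12, 4 of 11 and 5 of 13 members were at least 2-fold higher and 3, 1 and 1 lower. Members included Izumo1r 24.6-fold [17.0 to 36.9], Il10 15.5-fold [10.2 to 24.999] and Foxp3 1.32-fold [1.07 to 1.65] at day 7. Naive and recirculating lymphocyte genes had median log2 ratios of -0.40, -0.48 and -1.07 (percentiles 1.02, 0.08 and 0). 0 of 17, 0 of 17 and 0 of 17 members were at least 2-fold higher and 5, 4 and 9 lower. Members included Sell 0.143-fold [0.109 to 0.185] and S1pr1 0.248-fold [0.224 to 0.275] at day 7. The type 1 helper and effector list had median log2 ratios of -0.51, -0.28 and -0.05 (percentiles 0.17, 0.79 and 37.6). 1 of 20, 5 of 20 and 3 of 20 members were at least 2-fold higher and 6, 5 and 0 lower. Members included Il12rb2 0.253-fold [0.234 to 0.274] at day 3 and Hopx 3.68-fold [3.40 to 3.999] at day 7. Tissue residency genes had median log2 ratios of -0.42, -0.28 and 0.21 (percentiles 1.47, 2.32 and 85.9). 1 of 10, 0 of 10 and 0 of 10 members were at least 2-fold higher and 3, 3 and 0 lower. Members included Rgs1 0.218-fold [0.204 to 0.232] and Rgs2 0.220-fold [0.195 to 0.247] at day 1. Proliferation genes had median log2 ratios of -0.14, 0.99 and 0.78 (percentiles 1.04, 100 and 100). 0 of 37, 20 of 40 and 11 of 39 members were at least 2-fold higher and 0, 0 and 0 lower. Members included Top2a 2.98-fold [2.69 to 3.29] and Nusap1 3.97-fold [3.31 to 4.79] at day 3 and Cdc20 3.65-fold [3.08 to 4.35] and Birc5 3.12-fold [2.69 to 3.63] at day 7.

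Interferon-stimulated genes of T-like cells had median log2 ratios of 0.95, 0.45 and 0.28 (percentiles 100, 99.99 and 99.5). 16 of 34, 6 of 31 and 3 of 31 members were at least 2-fold higher and 0, 0 and 1 lower. Members included Isg15 9.85-fold [8.63 to 11.3] and Rtp4 6.92-fold [5.56 to 8.66] at day 1 and Irf1 2.73-fold [2.56 to 2.92] at day 7. The Ccl3-Ccr5 axis list gave -3.56, -2.85 and -0.06 (percentiles 0, 0 and 39.1) and chemokine receptors 0.11, -0.17 and -0.07 (percentiles 56.6, 10.6 and 41.6). Chemokine ligands gave 0.72, -1.06 and 0.27 (percentiles 99.98, 0 and 93). Of the ligands higher at day 1, Ccl2 was 62.7 and Ccl12 32.6 CPM, against 1354 and 629 CPM in monocyte/macrophage-like cells of that library. S100a9, a neutrophil and monocyte gene chosen here after its values were seen, was at 0.874, 97.0, 4.82 and 68.9 CPM in T-like cells at days 0, 1, 3 and 7. Glycolysis and hypoxia genes gave 0.42, 0.35 and 1.05 (percentiles 99.5, 98.7 and 100), with Aldoa 4.19-fold [3.94 to 4.45] and Ldha 3.86-fold [3.71 to 4.01] at day 7, and oxidative phosphorylation genes 0.43, 0.42 and 0.33 (percentiles 99.9, 99.8 and 98.8). MHC class I presentation gave 0.30, 0.37 and 0.44 (percentiles 93.9, 98.6 and 99.7). MHC class II presentation gave -0.27, -1.12 and -0.41 (percentiles 13.7, 0 and 3.57), at low levels: Cd74 was 465 CPM untransplanted and 317 at day 7, against 8565 and 12317 CPM in monocyte/macrophage-like cells. The dissociation and stress list gave -0.40, -0.72 and -0.56 (percentiles 1.19, 0.01 and 0.05), with Junb 0.304-fold [0.294 to 0.315] and Nr4a1 0.177-fold [0.166 to 0.189] at day 1, so the untransplanted library was higher in it here too. With no CPM minimum, the calls for chemokine ligands at day 3 (-0.04), interferon-stimulated genes at day 3 (0.14), the type 1 list at day 3 (-0.05), cytotoxic effectors at day 1 (-0.23) and naive genes at day 1 (-0.15) were lost. A pseudocount of 50 CPM ended those for proliferation at day 1 (-0.05) and MHC class I at day 3 (0.23), and a pseudocount of 1 CPM that for tissue residency at day 3 (-0.30).

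NK-like cells were compared at days 3 (110 cells) and 7 (182 cells) against 374 untransplanted cells, since day 1 held only 36. Those furthest above at day 3 were Hopx 15.2-fold [12.5 to 18.7], Ccl1 10.4-fold [8.48 to 12.7], Stmn1 8.11-fold [6.58 to 10.04], Ifi27 10.6-fold [6.93 to 16.6] and Icam1 6.95-fold [5.84 to 8.30], and those furthest below Rasgef1b 0.167-fold [0.140 to 0.198], B3gnt7 0.146-fold [0.0767 to 0.254], Mknk1 0.150-fold [0.0764 to 0.267], Nck2 0.154-fold [0.0811 to 0.269] and Scimp 0.198-fold [0.137 to 0.278]. At day 7 those above were Slc27a2 60.1-fold [29.9 to 141], Ifi27 18.8-fold [12.7 to 28.7], Gzmbl1 60.1-fold [22.8 to 225], Hopx 10.5-fold [8.62 to 12.99] and Gzmbl3 8.10-fold [6.56 to 10.1], of which Gzmbl1 and Gzmbl3 are granzyme genes. Below were Oplah 0.0947-fold [0.0427 to 0.183], B3gnt7 0.128-fold [0.0707 to 0.215], Nt5e 0.159-fold [0.105 to 0.232], Cab39l 0.190-fold [0.128 to 0.273] and Inpp4a 0.201-fold [0.142 to 0.278]. Nt5e is the surface enzyme CD73, which makes adenosine. Ccl3 stood at 0.781-fold [0.738 to 0.826] and 1.31-fold [1.26 to 1.37], Ccl4 at 0.626-fold [0.604 to 0.648] and 0.977-fold [0.951 to 1.003]. Ccl5 was at 1.32-fold [1.29 to 1.36] and 1.58-fold [1.54 to 1.61], and Ccr5 at 0.746-fold [0.610 to 0.908] and 0.690-fold [0.572 to 0.827].

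Cytotoxic effectors of NK-like cells had median log2 ratios of 0.46 and 0.74 (percentiles 99.7 and 100). 3 of 19 and 7 of 19 members were at least 2-fold higher and 0 and 1 lower at days 3 and 7. Members included Gzma 3.11-fold [2.90 to 3.33] and Gzmb 2.73-fold [2.55 to 2.93] at day 7. Proliferation genes had median log2 ratios of 1.21 and 0.00 (percentiles 100 and 70.5). 22 of 30 and 0 of 17 members were at least 2-fold higher and 0 and 0 lower. Members included Mcm5 8.52-fold [5.03 to 15.01] and Dut 4.67-fold [3.74 to 5.85] at day 3. Medians at days 3 and 7 were 0.37 and 0.68 (percentiles 99.5 and 100) for interferon-stimulated genes, 0.59 and 0.71 (percentiles 99.9 and 100) for MHC class I presentation. They were 0.44 and 0.61 (percentiles 99.5 and 100) for glycolysis and hypoxia and 0.59 and 0.25 (percentiles 99.98 and 99.3) for oxidative phosphorylation. They were -0.30 and 0.39 (percentiles 13.8 and 97.8) for chemokine ligands, -0.10 and 0.19 (percentiles 32.5 and 86.4) for chemokine receptors. For the Ccl3-Ccr5 axis they were -0.38 and 0.18 (percentiles 16.5 and 69.1), and 0.01 and 0.32 (percentiles 50.6 and 97.6) for inhibitory receptors, with Lag3 6.48-fold [4.48 to 9.56] and Ctla4 4.26-fold [3.26 to 5.59] at day 7. Tissue residency gave -0.35 and -0.33 (percentiles 6.44 and 10.8), MHC class II presentation -0.62 and -0.21 (percentiles 0.78 and 26.6) and dissociation and stress -0.30 and -0.32 (percentiles 5.33 and 2.46). The day 7 calls for chemokine ligands (0.40) and for stress (-0.32) were lost with a pseudocount of 1 CPM, that for stress also with median-of-ratios scaling (-0.30), and that for inhibitory receptors with a pseudocount of 50 CPM (0.19). S100a9 and the macrophage marker Lyz2, chosen after their values were seen, were at 1.51 and 113 CPM in untransplanted NK-like cells and at 86.5 and 343 CPM at day 7.

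In dendritic cell-like cells at day 1 (399 cells against 341), the genes furthest above were Isg15 69.6-fold [54.2 to 91.0], Lilrb4 55.7-fold [42.5 to 74.3] and Slc7a11 98.5-fold [58.5 to 181] and those furthest below Rasd1 0.0299-fold [0.0227 to 0.0386], Plxdc2 0.0231-fold [0.0156 to 0.0329] and Apobec1 0.0110-fold [0.00501 to 0.0210]. Slc7a11 imports cystine and Lilrb4 is an inhibitory receptor. At day 3 (516 cells) those above were Cxcl11, at 167 CPM from 0 UMIs and so at least 8.23 higher on the log2 scale against a floor of 3 counts, Timp1 52.0-fold [34.3 to 83.3] and Cxcl9 12.02-fold [9.78 to 14.9]. Those below were RT1-Bb 0.0286-fold [0.0275 to 0.0298], Apobec1 0.0105-fold [0.00570 to 0.0176] and Rasd1 0.0426-fold [0.0357 to 0.0506]. Ccr5 stood at 2.33-fold [1.98 to 2.74] and 4.18-fold [3.63 to 4.83] at days 1 and 3, Ccr1 at 4.47-fold [3.26 to 6.23] and 10.98-fold [8.24 to 14.9]. Ccl3 was at 0.574-fold [0.527 to 0.625] and 0.611-fold [0.568 to 0.656], Ccl4 at 0.361-fold [0.332 to 0.392] and 0.428-fold [0.401 to 0.457], and Ccl5 at 0.965-fold [0.750 to 1.24] and 0.173-fold [0.116 to 0.252]. The untransplanted class was 56.0% cluster 20, led by Xcr1 and Clec9a, which held 0 and 0.388% of the class at days 1 and 3, and day 1 was 44.6% cluster 21, led by Fscn1 and Ccl22. At day 7 only 13 cells were found, too few for values.

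Co-stimulation and maturation genes of dendritic cell-like cells had median log2 ratios of 1.25 and 0.47 (percentiles 100 and 95.4). 10 of 17 and 4 of 12 members were at least 2-fold higher and 1 and 1 lower at days 1 and 3. Members included Socs2 48.9-fold [30.7 to 83.0], Cd274 21.6-fold [15.3 to 31.5] and Cd83 0.281-fold [0.271 to 0.292] at day 1 and Ccl17 4.11-fold [3.62 to 4.69] at day 3. Interferon-stimulated genes had median log2 ratios of 1.32 and 0.89 (percentiles 100 and 100). 21 of 34 and 11 of 27 members were at least 2-fold higher and 0 and 0 lower. Members included Cxcl10 8.69-fold [7.60 to 9.98] at day 1 and Gbp2 14.1-fold [9.83 to 20.9] at day 3. Proliferation genes had median log2 ratios of 0.85 and 0.95 (percentiles 99.99 and 100). 7 of 20 and 10 of 22 members were at least 2-fold higher and 1 and 1 lower. Members included Stmn1 10.5-fold [8.31 to 13.5] and Mcm6 4.40-fold [3.603 to 5.42] at day 3. Medians at days 1 and 3 were 0.75 and -0.55 (percentiles 99.9 and 0.06) for chemokine ligands, 0.15 and 0.60 (percentiles 42.8 and 95) for chemokine receptors. For the Ccl3-Ccr5 axis they were -0.04 and -0.68 (percentiles 29.8 and 1.29), and -0.46 and 0.14 (percentiles 2.83 and 37.2) for proinflammatory cytokines. They were 0.47 and 0.54 (percentiles 92.8 and 97.47) for glycolysis and hypoxia, 0.79 and 0.97 (percentiles 99.9 and 100) for oxidative phosphorylation, 0.77 and 0.25 (percentiles 99.6 and 61) for MHC class I presentation and -1.01 and -0.76 (percentiles 0.22 and 0.44) for MHC class II presentation. Tubular RNA gave 0.79 and 0.56 (percentiles 93.6 and 90.3), and the dissociation and stress list -0.99 and -0.71 (percentiles 0.02 and 0.11). S100a9 was at 1.30, 54.7 and 3.34 CPM in this class at days 0, 1 and 3. The chemokine ligand call at day 3 was lost with no CPM minimum (-0.08).

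B-like cells were few (147, 124, 283 and 380 by day), which UMI-based intervals leave out. At day 1 the genes furthest above were Ifi27 28.8-fold [14.2 to 68.2], RT1-T24-3 20.9-fold [10.97 to 44.7] and Creld2 17.5-fold [9.41 to 36.2], and those furthest below Scml4 (0.0395-fold [0.0220 to 0.0656]), Parm1 (0.0446-fold [0.0143 to 0.106]) and Chrne, which went from 157 CPM to 0 UMIs, a log2 ratio of -4.35 at a floor of 3 counts. At day 3 those above were Cxcl10 177-fold [31.5 to 6986], Gimap4 30.1-fold [14.5 to 75.3] and Ifi47 48.0-fold [13.2 to 398] and those below Scml4 0.0587-fold [0.0479 to 0.0713], Ccl3 0.0809-fold [0.0716 to 0.0912] and Dusp10 0.0915-fold [0.0765 to 0.109]. At day 7 those above were Cxcl10 122-fold [21.8 to 4855], Igtp 14.95-fold [7.75 to 33.1] and Ifi27 13.2-fold [6.59 to 31.1]. Below at day 7 were Ahnak 0.233-fold [0.154 to 0.348], Ezh2 0.270-fold [0.188 to 0.385] and Klf2 0.319-fold [0.227 to 0.445], where Klf2 is a transcription factor of resting lymphocytes. Cxcl10, Ifi47, Igtp and Ifi27 are interferon-induced. Ccl3 stood at 0.107-fold [0.0847 to 0.134] at day 1 and 0.941-fold [0.881 to 1.01] at day 7. Beside it Lyz2, a monocyte and macrophage marker chosen after its values were seen, was at 965, 704, 105 and 440 CPM in B-like cells at days 0, 1, 3 and 7. Ccl4 was at 0.0965-fold [0.0701 to 0.130], 0.0424-fold [0.0344 to 0.0518] and 0.477-fold [0.433 to 0.527]. Ccl5 was at 0.124-fold [0.0144 to 0.491], 0.588-fold [0.366 to 0.962] and 0.767-fold [0.467 to 1.28]. Ccr5 was at 2.93-fold [1.51 to 5.84], 4.89-fold [2.95 to 8.70] and 0.497-fold [0.229 to 1.07]. Ccr1 was at 0 [0 to 5.26], 12.9 [4.17 to 30.0], 71.6 [60.6 to 84.0] and 3.78 [1.23 to 8.82] CPM at days 0, 1, 3 and 7.

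Interferon-stimulated genes of B-like cells had median log2 ratios of 1.36, 1.07 and 1.21 (percentiles 100, 100 and 100). 21 of 32, 17 of 32 and 18 of 32 members were at least 2-fold higher and 2, 0 and 0 lower. Members included Mx2 28.2-fold [9.09 to 142] and Irf7 10.6-fold [5.58 to 22.4] at day 1 and Irf1 7.88-fold [6.21 to 10.2] at day 7. MHC class I presentation had median log2 ratios of 0.69, 1.30 and 0.93 (percentiles 99.7, 100 and 100). 6 of 16, 10 of 17 and 7 of 16 members were at least 2-fold higher and 0, 0 and 0 lower. Members included Psmb9 4.89-fold [3.93 to 6.17] and Psme2 4.71-fold [3.58 to 6.31] at day 3 and Tap1 6.46-fold [4.58 to 9.41] at day 7. B cell activation genes had median log2 ratios of -0.44, -0.10 and 0.09 (percentiles 1.13, 31.6 and 79.8). 5 of 20, 7 of 22 and 1 of 18 members were at least 2-fold higher and 8, 5 and 1 lower. Members included Mzb1, a gene of antibody-secreting cells, at 8.001-fold [6.14 to 10.6] and Cd83 at 0.305-fold [0.287 to 0.324] at day 3. Naive and recirculating lymphocyte genes had median log2 ratios of -0.73, -1.35 and -0.30 (percentiles 0.35, 0 and 1.71). 0 of 14, 1 of 15 and 0 of 14 members were at least 2-fold higher and 4, 11 and 3 lower. Members included Satb1 0.139-fold [0.124 to 0.156] and Foxo1 0.248-fold [0.214 to 0.287] at day 3. Chemokine receptors gave 0.22, 1.89 and 0.26 (percentiles 48.9, 100 and 89.6), with Cxcr3 39.8-fold [10.9 to 330.4], Ccr6 5.07-fold [3.48 to 7.66] and Cxcr4 0.155-fold [0.142 to 0.170] at day 3. Medians were 0.25, 0.65 and -0.12 (percentiles 59.6, 99.99 and 22.9) for proliferation, 0.68, 0.95 and 0.53 (percentiles 99.5, 100 and 100) for glycolysis and hypoxia, 1.01, 0.90 and 0.26 (percentiles 100, 100 and 99.8) for oxidative phosphorylation and 0.27, -0.27 and 0.20 (percentiles 86.3, 16.4 and 86.4) for MHC class II presentation. They were 0.84, -1.44 and 0.13 (percentiles 99.8, 0 and 75.3) for chemokine ligands, -1.76, -0.58 and -0.46 (percentiles 0.105, 9.65 and 2.52) for the Ccl3-Ccr5 axis and -1.10, -1.55 and -0.30 (percentiles 0, 0 and 0.47) for dissociation and stress. Beside the chemokine ligands, S100a9 was at 2.85, 123, 4.77 and 91.5 CPM in B-like cells at days 0, 1, 3 and 7, and at 13.5, 1065, 54.5 and 185 CPM in monocyte/macrophage-like cells. With a pseudocount of 50 CPM the day 1 calls for chemokine ligands (0.25) and B cell activation (-0.20) were lost.

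MHC class II genes, which present peptides to helper T cells, were lower in monocyte/macrophage-like cells at days 1 and 3. The list had median log2 ratios of -1.51, -1.35 and 0.09 (percentiles 0, 0.005 and 77.8). 0 of 11, 1 of 11 and 2 of 11 members were at least 2-fold higher and 8, 8 and 2 lower. Cd74, the invariant chain, went from 8565 CPM to 3003, 3475 and 12317 CPM, and RT1-Ba from 3508 to 1013, 1096 and 3637 CPM. RT1-Bb, the beta chain that pairs with RT1-Ba, went from 3760 to 993, 326 and 207 CPM. In B-like cells RT1-Ba was 2019, 1635, 1826 and 2601 CPM at days 0, 1, 3 and 7 and RT1-Bb 2348, 288, 132 and 126 CPM. In dendritic cell-like cells RT1-Ba was 9873, 4904 and 4321 CPM at days 0, 1 and 3, and RT1-Bb 12543, 4243 and 359 CPM. RT1-Bb was picked out for this comparison after its values were seen. RT1 genes are polymorphic between rat strains, allografts can hold cells of donor and recipient, and reads of some alleles can go uncounted, so RT1 values between libraries are limited by that. The identifiers were ENSRNOG00000018735 (Cd74), ENSRNOG00000000451 (RT1-Ba) and ENSRNOG00000032708 (RT1-Bb).

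**Figure D3:**
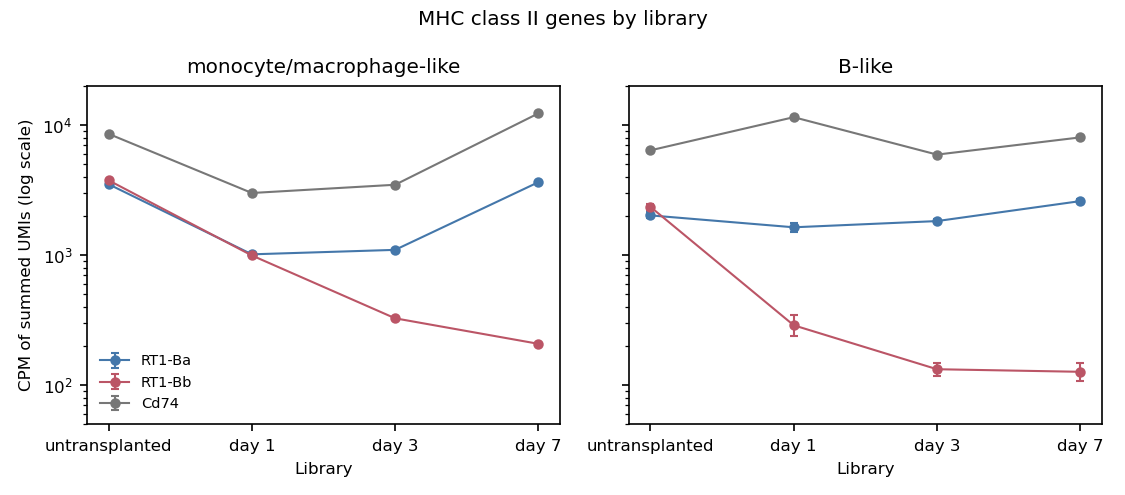
CPM (log axis) of 3 MHC class II genes, Cd74, RT1-Ba and RT1-Bb, in monocyte/macrophage-like and B-like cells at days 0, 1, 3 and 7, with exact 95% Poisson intervals, 1 library per day. In monocyte/macrophage-like cells at day 7, RT1-Ba was 3637 CPM and RT1-Bb 207 CPM.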

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

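Tests chosen only after the result was seen were those of free RNA or doublets in T-like cells and of strain variants with Cd74 and Ciita, as well as the choice of RT1-Bb, S100a9 and Lyz2 and the split by day of the T-like cluster test. With 1 library per group, none of the differences between days named here was tested.

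Several results had opposite directions at different days against the untransplanted library. The share of T-like cells had a log2 ratio of -0.96 at day 1, 0.15 at day 3 and 0.22 at day 7. That of monocyte/macrophage-like cells was 0.11, -0.19 and -0.38, but -0.088 at day 1 with classes given cell by cell, which leaves no opposite direction. That of dendritic cell-like cells was 0.30, 0.25 and -5.19. The median log2 ratio of chemokine ligands was 0.72 at day 1 and -1.06 at day 3 in T-like cells, 0.75 and -0.55 in dendritic cell-like cells, and 0.84 and -1.44 in B-like cells. The T-like and dendritic cell-like results at day 3 came within random lists with no CPM minimum (-0.04 and -0.08), and the B-like one at day 1 with a pseudocount of 50 CPM (0.25). S100a9, a neutrophil and monocyte gene, rose at day 1 too and had fallen by day 3, at 0.874, 97.0 and 4.82 CPM in T-like, 1.30, 54.7 and 3.34 CPM in dendritic cell-like and 2.85, 123 and 4.77 CPM in B-like cells at days 0, 1 and 3. Proliferation genes of T-like cells were at -0.14, 0.99 and 0.78 at days 1, 3 and 7, and their cytotoxic effectors at -0.36, -1.27 and 0.64. Both day 1 results came within random lists, the first with a pseudocount of 50 CPM (-0.05) and the second with no CPM minimum (-0.23). Inhibitory receptors of T-like cells were at -0.25 at day 3 and 0.85 at day 7. Proinflammatory cytokines of monocyte/macrophage-like cells were at -0.79 at day 1 and 1.38 at day 7, but at 0.027 at day 1 with no CPM minimum, which turns the direction. Outside the named classes, cluster 15 held more of the kept cells in each allograft library, 4.32% at day 1, 2.32% at day 3 and 2.503% at day 7, than in the untransplanted one (0.999%).

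Ccl3 was lower in monocyte/macrophage-like cells at days 1 and 3, with log2 ratios of -1.25 and -2.51. Within cluster 0, where only 268 cells were untransplanted, the ratios were -0.11 and -0.31. In clusters made without the genes of the lists concerned they were -0.12 and -0.30. A change in the clusters that make up the class would give such small ratios. Clusters hold cells that are alike, so a change of state or a library difference that moves cells between clusters would give them too. The values within clusters cannot tell these apart. A stronger dissociation and stress response in the untransplanted library could not be decided, since the stress list lay at percentiles of 1.19 and 0.01 in T-like cells but 5.33 in the 110 NK-like cells at day 3, with 1.66 to 12.51 at the ends of its counting interval. Ccl3 is itself induced by such stress, so this explanation stays open, as does a difference between single sorts or digestions. An effect of transplantation and of the day on which cells are in the kidney is the biological explanation the design names, and it was not tested.

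The MHC class II list was lower in the same cells at days 1 and 3, with medians of -1.51 and -1.35. Within cluster 0 the medians were 0.027 and -0.20 (0.04 and -0.09 in clusters made without these genes). A change in the clusters that make up the class would give this. As for Ccl3, a change of state or a library difference that moves cells between clusters would give it too. Strain variants that change how RT1 reads are counted could not be decided, as Cd74 was at -1.51 and -1.30 but Ciita at -0.09 and 1.27. RT1-Bb relative to RT1-Ba had log2 ratios of -4.23 in monocyte/macrophage-like and -4.58 in B-like cells at day 7, for which a variant of RT1-Bb that separates donor from recipient cells stays open: of 217 dendritic cell-like cells at day 1, 46.1% had an RT1-Bb share at or above the untransplanted bound of 46.9%, 32.3% at or below the day 3 bound of 12.2%, and 21.7% [16.4 to 27.7] lay between, against a limit of 20%. The effect of transplantation stays open too and was not tested.

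Ccl3 and Ccl4 were lower in T-like cells, with log2 ratios of -3.41 and -3.75 at day 1 and -3.72 and -3.599 at day 3. Free RNA or doublets of monocyte/macrophage-like cells in the untransplanted library are argued against, since 5 abundant markers of that class had in T-like cells a median of 1.49% (highest 1.58%) of their level there, and Ccl3 had 97.2% and Ccl4 125%. A change in the clusters that make up the class is argued against at day 1, when Ccl3 was at -2.93 and Ccl4 at -3.17 within cluster 5. At day 3 they were at -1.57 and -1.40 within it, as such a change would give for most of the difference. A change of state or a library difference that moves cells between clusters would give this too, so day 3 is not decided. Clusters made without the listed genes gave -2.90 and -3.18 at day 1 and -1.62 and -1.48 at day 3. The stress response, whose list was also lower in these cells, and the effect of transplantation, which was not tested, stay open.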

How the results depend on the processing

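Alternatives chosen after seeing the data were the doublet threshold that Scrublet sets itself, naming the low-UMI cluster 15 by its markers, median-of-ratios scaling for named genes, and days 1 and 3 as reference libraries. As each group is 1 library, no paired analysis was possible and no library could be left out. A value counts here as kept when it stayed within its 95% counting interval, which is narrow at these depths. A reversal was counted only where the whole interval of the first value had the same sign. For a list, its median also had to lie in the lowest or highest 2.5% of random lists. Changes of sign in other values are counted as kept or moved.

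Of 90 log2 ratios of class shares under alternatives, 81 stayed within the interval of the first value, 8 moved beyond it in the same direction and 1 was reversed. Classes given cell by cell from markers took the monocyte/macrophage-like ratio to -0.088 at day 1, a reversal, and to -0.43 at day 3. They took the neutrophil-like ratio to 3.39 at day 1 and 2.17 at day 3, and the T-like ratio at day 1 to -0.69. The T-like ratio was -0.49 at day 1 when cluster 15 was counted by its markers, and 0.036 and 0.085 at days 3 and 7 with doublets kept. The neutrophil-like ratio at day 3 was 1.13 with at least 500 genes per cell, a limit that shallow neutrophil-like cells meet less often. For the other settings the cause was not tested.

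For Ccl3 in monocyte/macrophage-like cells and Ccr5 in T-like cells, 56 of 78 values stayed within the interval, 20 moved beyond it and 2 were reversed. Ccl3 at day 1 was at -1.38 with classes cell by cell, -1.22 with a mitochondrial limit of 10%, -1.29 with doublets kept, -1.23 with 50 components, -1.27 with the threshold Scrublet sets, -1.40 with median-of-ratios scaling and -1.003 as a mean of single cells. At day 3 it was at -2.62 with classes cell by cell, -2.49 with 50 components and with the Scrublet threshold alike, -2.65 with median-of-ratios scaling and -1.55 as a mean of single cells. At day 7 it was at -0.50 with classes cell by cell and with doublets kept, -0.49 with a mitochondrial limit of 25%, -0.51 with the Scrublet threshold and -0.33 without the 10 genes with the most UMIs. It was reversed at day 7 by median-of-ratios scaling (0.0038) and as a mean of single cells (0.014), so its direction at day 7 is not settled, and the cause was not tested. Ccr5 in T-like cells was at -0.60 at day 3 with doublets kept and -0.80 with median-of-ratios scaling, and at 0.078 at day 7 as a mean of single cells, where its first interval held 0. The cause was not tested.

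Of 760 list medians under alternatives, 398 stayed within the interval, 361 moved beyond it, and 1 was reversed: proinflammatory cytokines in monocyte/macrophage-like cells at day 1, at 0.027 (percentile 58.9) with no CPM minimum, which adds low members to the list. Of the 122 list results in the lowest or highest 2.5% of random lists, 1 came inside with median-of-ratios scaling, 3 with a pseudocount of 1 CPM, 8 with 50 CPM and 10 with no CPM minimum, and 2, 2, 5 and 4 others went outside. Of the named genes under median-of-ratios scaling, 107 stayed within the interval, 53 moved and 1 was reversed, Ccl3 in monocyte/macrophage-like cells at day 7. With doublets kept, 77 CPM values of ligands and receptors stayed within the interval and 68 moved, and innate lymphoid cell-like cells gave no value, since no cluster then took that name. Without thinning, 40 shares of cells with a UMI stayed and 115 moved. Of percents of kept cells, 62 stayed and 14 moved.

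Depth limits the rarer classes most. NK-like cells at day 1, neutrophil-like and plasmacytoid dendritic cell-like cells in the untransplanted library and dendritic cell-like cells at day 7 held fewer than 100 cells, so their genes were not compared with the untransplanted library.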

Other observations

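Neutrophil-like and plasmacytoid dendritic cell-like cells were too few in the untransplanted library (74 and 25 cells) for a comparison with it, so they were compared between allograft days, a choice made after the data were seen. Neutrophil-like cells at day 7 (1904 cells) had higher inflammatory genes than at day 3 (300 cells). Ccl3 was 29.1-fold [24.5 to 34.7] and Cxcl2, which attracts neutrophils, 34.9-fold [31.4 to 38.8] of day 3, with Cxcl2 at 30834 CPM. Il1b was 22.7-fold [19.1 to 27.2], Il23a 25.7-fold [11.8 to 70.2] and Cxcl1 103-fold [49.8 to 255]. Median log2 ratios were 2.42 for chemokine ligands, 2.40 for proinflammatory cytokines, 2.198 for glycolysis and hypoxia, 1.91 for MHC class I presentation and 1.30 for interferon-stimulated genes (percentiles 100 for each), and -1.25 for proliferation (percentile 0.01). The neutrophil activation and granule list was at 0.20 (percentile 88.2), with 10 of 22 members at least 2-fold higher and 5 lower: the granule genes Ngp and Camp were at 0.00205-fold [0.00123 to 0.00323] and 0.0372-fold [0.0348 to 0.0397]. Ccl4 was 3.35-fold [2.26 to 5.19], Ccl5 3.02-fold [1.37 to 8.30], Ccr5 0.355-fold [0.135 to 1.18] and Ccr1 0.924-fold [0.805 to 1.07]. Against day 1 (343 cells), Ccl3 at day 7 was 15.8-fold [14.3 to 17.4] and Vegfa 10.8-fold [7.06 to 17.5], and the medians were 2.52 for proinflammatory cytokines (percentile 100), 0.86 for glycolysis and hypoxia (99.96), -0.21 for chemokine ligands (47.9), -0.57 for interferon-stimulated genes (3.64) and 0.13 for neutrophil activation and granule genes (82.9). Day 3 against day 1 gave 0.10 for the last list (18.1), -1.48 for interferon-stimulated genes and -1.56 for chemokine ligands (0 for both). Cluster 3 held 97.1% of neutrophil-like cells at day 7 and cluster 16 held 81.3% and 99.3% at days 1 and 3, so these differences are also between clusters, at median depths of 1565, 1029.5 and 3007 UMIs.

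Plasmacytoid dendritic cell-like cells at day 3 (594 cells) had lower interferon-stimulated genes than at day 1 (186 cells), with a median log2 ratio of -1.09 (percentile 0) and Isg15 at 0.0532-fold [0.0288 to 0.0936]. Isg15 was at 90.6 and 4.82 CPM in them at days 1 and 3 and at 3663 and 80.4 CPM in neutrophil-like cells, so free RNA is not excluded for Isg15. Their chemokine ligands were at -1.27 (percentile 0), though Xcl1 was 6.96-fold [5.07 to 9.83]. Among the lower ligands, Ccl2 went from 101 to 13.6 and Ccl12 from 51.5 to 0.283 CPM, and monocyte/macrophage-like cells of day 1 had 1354 and 629 CPM of them. Ccl3 was 0.562-fold [0.446 to 0.712], Ccl4 2.77-fold [2.25 to 3.43], Ccr5 1.66-fold [1.25 to 2.23] and Ccr1 0.0911-fold [0.0196 to 0.358] of day 1, and Ccl5 had 0 UMIs at day 1 and 19 at day 3. The dissociation and stress list was at 0.91 (percentile 100).

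In monocyte/macrophage-like cells, day 7 against day 3 gave Ccl3 at 4.08-fold [4.03 to 4.14] and Ccl4 at 4.37-fold [4.28 to 4.46], with Ccl5 at 3.84-fold [3.38 to 4.38], Ccr5 at 0.773-fold [0.746 to 0.8002] and Ccr1 at 0.311-fold [0.294 to 0.329]. Medians were 1.17 for the Ccl3-Ccr5 axis (percentile 99.8), 1.18 for MHC class II presentation (99.99) and -1.40 for proliferation (0). In T-like cells Ccl3 at day 7 was 10.9-fold [10.6 to 11.2], Ccl4 11.6-fold [11.4 to 11.8], Ccl5 5.28-fold [5.18 to 5.39], Ccr5 1.55-fold [1.46 to 1.65] and Ccr1 1.71-fold [1.14 to 2.62] of day 3.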
